A study of Mus musculus with 2 samples.

How the data were processed

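RNA was measured in 2 libraries of v6.5 mouse ES cells, 1 labelled wild-type and 1 labelled T29I mutant, so there was 1 library per group. The cell line name is that of the source label, and the strain label gives another name that could not be reconciled with it. Per the labels' protocols, RNA was extracted with Isogen and libraries were made with the Illumina TruSeq Stranded Total RNA kit with Ribo-Zero, which removes ribosomal RNA and keeps the strand of each transcript. The authors deposited 1 table with a gene symbol, an Ensembl gene identifier and a TPM value per gene and library. TPM (transcripts-per-million) divides the reads of a gene by its length and scales each library to a fixed sum, and each deposited column summed to 1000000. The aligner, the counting tool, the genome build, the annotation release and the sequencing length are not given in the sources used here. The columns were assigned to samples through the sample descriptions in the labels. Groups came from the genotype labels.

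Because each library is scaled to the same sum, a few abundant RNAs that take more of 1 library lower the TPM of all other genes there. TPM also keeps any difference between libraries in RNA integrity, fragment size or amplification, which acts through transcript length and GC content. Total RNA libraries include unspliced and non-polyadenylated transcripts. Genes with near-identical copies can gain or lose reads to those copies, depending on how multiply mapping reads were treated by the authors, which is not given in the sources used here.

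Gene identifiers were matched to GENCODE M21 (GRCm38). Of 51826 identifiers 51633 matched and 193 did not, and the unmatched genes held 400.1 TPM in the wild-type library and 126 TPM in the T29I library. The annotation gave each gene its type, chromosome, merged exon length, longest transcript and GC content, and 99.8% of the genes with a mean of at least 1 TPM had a GC value. The build used by the authors may not be GRCm38, and coordinates are those of GENCODE M21. Multiplying TPM by merged exon length and dividing by the value of 1 read gave a whole number, within a tolerance of 0.05, for 81.0% of values in the wild-type library and 79.9% in the T29I library, against 10% by chance. The value of 1 read was 1.27 times as large in the wild-type library as in the T29I library by this length-based estimate. Without lengths, the commonest ratio of wild-type to T29I TPM across genes, shared by 569 genes, came to 1.27 too. The resulting estimates of 16909966 and 15281605 reads were used for counting intervals and for the estimated reads of single genes and gene pairs. The counting intervals are 95% exact Poisson intervals and cover counting error only. No fold is given against a library where a gene is listed at 0, because a listed 0 in a TPM file can also come from masking or mapping. No count model was fitted, because the deposited values are TPM and 1 library per group leaves no spread to estimate.

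The comparison used the log2 ratio of T29I over wild-type on the log2(TPM + 1) scale, which understates differences of low genes. The size rule, fixed before the data were examined, was a log2 ratio of at least 1 in either direction among genes with a mean of at least 1 TPM. TPM values of the 2 libraries are printed in the order wild-type, then T29I. The shift was the median log2 ratio of genes with a mean of at least 5 TPM, and "relative to the shift" means after subtracting it. A list median between 0 and 0.90 relative to the shift was thus at or below 0 as deposited. The length and GC adjustment, chosen after seeing the data, took residuals of a quadratic fit with interaction on log2 longest-transcript length and GC content, fitted on protein-coding genes with a mean of at least 5 TPM. It removes any true difference that follows length or GC content, as well as bias. The longest annotated transcript need not be the one expressed, so adjusted values of single genes can rest on a wrong length. Ratios of low genes are compressed by the log2(TPM + 1) scale, while the trend was fitted on genes with a mean of at least 5 TPM. For such low genes the adjustment can therefore remove more than the trend.

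The 35 gene lists were fixed before the data were examined, and each list with at least 5 members of mean TPM at least 1 was set against 10000 random lists of the same size matched on mean expression in 20 bins. A percentile of 100 or 0 means above or below all or nearly all of them. Intervals of medians of lists, length and GC classes and chromosomes are 95% binomial intervals over genes, which describe spread between genes of these 2 libraries and not between cultures. Chromosome medians used genes with a mean of at least 5 TPM, and windows hold about 25 neighbouring genes.

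Genes were named by a rule fixed before the data were examined. It took Prss1 and the trypsinogen list, all core pluripotency factors, and the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 TPM. It also took up to 2 highest and 2 lowest measured members of each list, and the members at least 2-fold apart where a list had 6 or fewer. For the ranking of 8882 genes, 493 small RNAs and predicted or clone-named genes were left out, 7 of which would have been among the 12 lowest and 5 among the 12 highest. A few genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

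The steps were tested on simulated data with 200 altered genes and the observed trend with length and GC content, over 13030 genes of the T29I and wild-type comparison. With a simulated log2 fold of 2.0 the size rule called 77% of altered genes in the right direction as deposited, 74% after centring and 97% after adjustment. Of simulated genes with no true difference, 33.4% were called as deposited, 24.3% after centring and 0.757% after adjustment. The simulated trend had the same form as the adjustment, and only counting noise was added. The rates after adjustment thus follow from the design of the simulation and do not carry over to the real libraries. Alternatives were other pseudocounts (0.1 and 5), other minimum values, median centring, TMM and upper-quartile scaling, leaving out small RNAs and predicted genes, and the length and GC adjustment. TMM factors were computed without weights, trimming 30% of log ratios and 5% of levels at each end. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9.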

Results

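Total RNA was sequenced from v6.5 cells, a line of mouse embryonic stem (ES) cells, in 1 wild-type library and 1 library from cells carrying a T29I mutation. The labels name the PRSS1 gene and T29I, and the mutated gene is taken here to be mouse Prss1. ES cells are pluripotent cells derived from the early embryo. Prss1 encodes a trypsinogen, the inactive precursor of the digestive protease trypsin, which is made by the acinar cells of the pancreas. The comparison of the 2 libraries addresses how the transcriptome of the mutated ES cells differs from that of the wild-type cells. Of 51826 listed genes, 19332 were above 0 in the wild-type library and 17704 in the T29I library, and 13174 and 11590 genes reached 1 TPM (transcripts-per-million, a length-scaled abundance). The estimated depth was 16909966 and 15281605 reads assigned to genes. The 20 most abundant genes held 16.9% of the wild-type TPM and 27.0% of the T29I TPM. Spearman's rho between the libraries was 0.759 across the 12943 genes with a mean of at least 1 TPM, and genes are not independent replicates. With 1 library per group nothing in the comparison is replicated, so "higher" and "lower" describe these 2 libraries and no p-value is given. Genotype, clone, culture and library preparation all differ, or can differ, between the 2 libraries at once.

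Prss1, taken as the mutated gene, was listed at 0 TPM in both libraries. In GENCODE M21 on the GRCm38 build, Prss1 (ENSMUSG00000062751) lies on the + strand of chromosome 6 from 41458932 to 41463786 and has 5 exons. Codon 29 of its annotated coding sequence is ACC, for threonine, in exon 2 at 41461225 to 41461227, so T29I fits the reference residue. The upper counting bounds for Prss1 were 0.883 TPM in the wild-type library and 0.694 TPM in the T29I library. In both libraries 24 mitochondrial rRNA and tRNA genes, which every cell uses, were listed at 0 too. A listed 0 thus does not by itself show that a gene was not expressed. Because the kit removes ribosomal RNA, however, the rRNA zeros say little about an mRNA such as Prss1. The close relatives of Prss1, namely Prss2, Prss3, Try4, Try5 and Try10, were listed at 0 as well, as was Tmprss15, the enteropeptidase that activates trypsinogen. Of the 20 listed genes in the trypsinogen and trypsin-related list, 14 were at 0 in both libraries and 4 had a mean of at least 1 TPM. Among those 4, Spink1, a trypsin inhibitor, was at 35.6 TPM in the wild-type library and 2.87 TPM in the T29I library. F2rl1, which encodes a receptor cleaved by trypsin, was at 62.5 and 23.2 TPM. The lysosomal proteases Ctsl and Ctsb were at 47.6 and 28.8 TPM and at 49.9 and 43.9 TPM, with adjusted log2 ratios of 1.37 and 1.23 in the other direction once length and GC content were taken into account. Ctrc was listed at 0 in both libraries. With Prss1 at 0 and no base calls in the values, the level of the gene is no check of the genotype labels or of which trypsinogen gene was edited.

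The genes that differed most included Tfcp2l1 and Tet2, which were lower in the T29I library, and Hbb-bs, H19 and Hand1, which were higher. The ranking took genes with a mean of at least 5 TPM, without small RNAs and predicted or clone-named genes. Its 12 lowest ratios included Tfcp2l1, a transcription factor of naive pluripotency, at 194 TPM in the wild-type library and 3.11 TPM in the T29I library. Also among the lowest were Tet2, a 5-methylcytosine dioxygenase, at 62.1 and 0.489 TPM, and Inhbb, an activin subunit, at 81.1 and 1.07 TPM. Triml2 was at 138 and 0.876 TPM, Ccnb1ip1 at 57.7 and 0.602 TPM, and the zinc finger genes Zfp978 and Zfp986 at 194 and 1.65 and at 102 and 1.27 TPM. Zfp640, annotated as a transcribed processed pseudogene, was at 85.1 and 0.934 TPM. The 12 highest included H19, an imprinted non-coding RNA, at 8.61 TPM in the wild-type library and 967 TPM in the T29I library. Hand1, a transcription factor of trophoblast and mesoderm, was at 0.868 and 79.5 TPM, and Krt19, a keratin of simple epithelia, at 2.91 and 84.1 TPM. Ndufa4l2 was at 0.704 and 78.4 TPM, Fyb at 0.0371 and 43.8 TPM, Mt3, a metallothionein, at 1.45 and 56.4 TPM, Car4 at 4.31 and 119 TPM, and Igfbp4 at 1.26 and 50.3 TPM. The histone genes Hist1h3h, Hist1h2bj and Hist1h2ag were at 0, 0.832 and 0 TPM in the wild-type library and at 44.9, 56.6 and 20.9 TPM in the T29I library. Hbb-bs, an adult beta-globin gene, was listed at 0 in the wild-type library and at 1245 TPM in the T29I library. Which sequence gave the reads assigned to Hbb-bs was not tested.

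Another 3 genes among the lowest ratios each share sequence or reads with a second gene, and their values are uncertain. Eno1b was at 2375 and 20.8 TPM while Eno1, the glycolytic enolase, was at 989 and 4114 TPM, and the pair summed to 3364 and 4135 TPM. That sum adds values scaled by unlike merged exon lengths, 1877 bases for Eno1b and 5379 for Eno1. In estimated reads the pair was at 50756 in the wild-type library and 146441 in the T29I library. Pcna-ps2 was at 169 and 0.723 TPM while Pcna was at 466 and 231 TPM, with sums of 635 and 232 TPM. Snurf was at 103 and 0 TPM while Snrpn, which it overlaps, was at 194 and 346 TPM, with sums of 297 and 346 TPM. Snurf is annotated at only 216 bases, and its 103 TPM came from an estimated 115 reads, against 2175 for Snrpn in the same library. The Snrpn pair was at an estimated 2290 and 4939 reads, so its TPM sums understate the difference. Pcna and Snrpn were added as partners after their values were seen.

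Most genes had a lower TPM in the T29I library, and the difference followed transcript length and GC content. Of the 12943 genes, 1290 were at least 2-fold higher and 5909 at least 2-fold lower in the T29I library on the log2(TPM + 1) scale. The median log2 ratio of the 9375 genes with a mean of at least 5 TPM was -0.90, which is 1.86-fold lower. Measured relative to this shift, 3371 genes were at least 2-fold higher and 2867 at least 2-fold lower, and the higher genes made up 54.0% of these genes instead of 17.9%. Among 9100 protein-coding genes, Spearman's rho of the log2 ratio across genes was -0.53 with the length of the longest transcript and 0.56 with its GC content. The shortest 20% of genes had a median log2 ratio of 0.26 (95% interval 0.18 to 0.33) and the longest 20% -2.05 (-2.11 to -1.996). By GC content, the lowest 20% had a median of -1.78 (-1.85 to -1.72) and the highest 20% 0.34 (0.28 to 0.39). Length and GC content together accounted for 44.9% of the variance of the log2 ratios. After adjustment for both, 2268 genes were at least 2-fold higher and 2003 at least 2-fold lower, of 12920 genes with a GC value. For some named genes most of the difference relative to the shift followed the trend, as judged by their longest annotated transcript. That transcript is 4059 bases for Rps24, and whether it was the one expressed was not tested. The adjusted log2 ratio was -0.21 for Atf6, -0.61 for Il17rd, -0.57 for Rps24, -0.50 for mt-Nd4l, 0.0056 for Bik, 0.058 for Rpl29, 0.16 for Fgf8 and 0.38 for Hmox1. The long nuclear RNA Malat1, chosen after its values were seen, was at 110 and 6.52 TPM. By annotated type, the median log2 ratio was -1.60 for 273 lincRNA genes and -0.80 for 12121 protein-coding genes. The gene lists are therefore described relative to the median shift, with the length and GC adjusted value beside it.

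**Figure D1:**
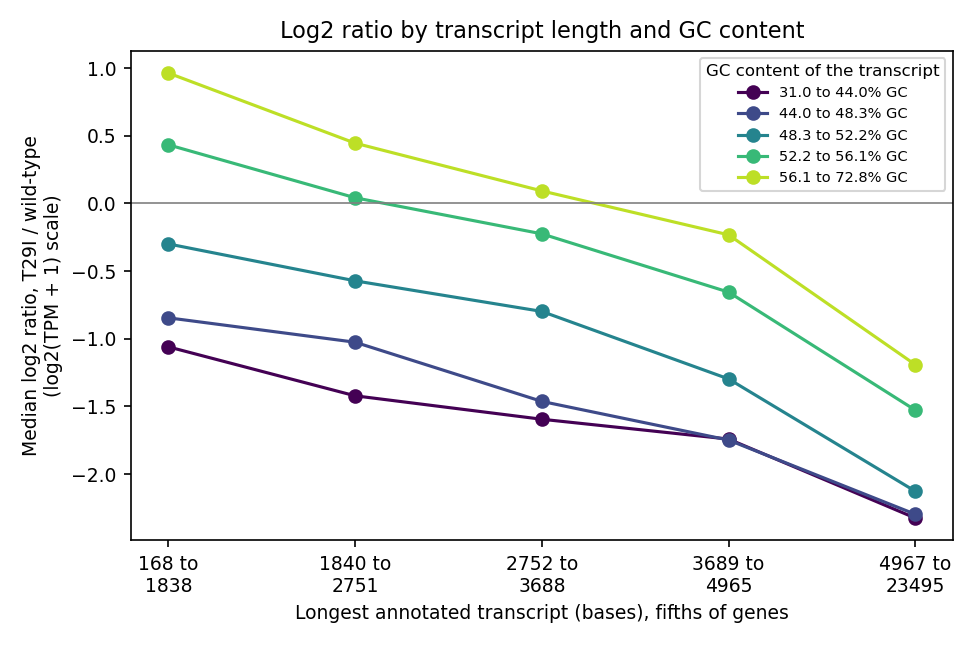
Median log2 ratio (T29I over wild-type, log2(TPM + 1) scale) of protein-coding genes with a mean of at least 5 TPM, in 5 equal classes of longest-transcript length in bases on the x axis and with 1 line per class of GC content. The medians run from 0.96 in short genes of high GC content to -2.33 in long genes of low GC content.

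Naive pluripotency markers were lower in the T29I library, while primed markers tended to be higher. Naive ES cells resemble the epiblast before implantation and primed cells the epiblast after it. Relative to the median shift, 10 of the 16 naive markers were at least 2-fold lower and 2 at least 2-fold higher, with a list median of -1.60. That median lay below those of all 10000 random lists matched on expression (percentile 0), and the adjusted median was -1.61 (95% interval -3.01 to -0.89). The lowest members were Tfcp2l1 and Zfp42, the latter at 544 TPM in the wild-type library (counting interval 529 to 559) and 23.3 TPM in the T29I library (20.7 to 26.2). Klf4, a reprogramming factor, was at 186 and 11.02 TPM, and Esrrb, Nr5a2 and Prdm14 were at 313 and 77.5, 49.1 and 2.80, and 36.0 and 4.19 TPM; Esrrb, Nr5a2 and Prdm14 were chosen after their values were seen. Against the direction of the list, Dppa3 was at 72.6 and 153 TPM and Klf2 at 303 and 348 TPM, although the adjusted log2 ratio of Klf2 was -0.89. Of the 14 primed markers, 10 were at least 2-fold higher relative to the shift and 0 at least 2-fold lower, with a median of 1.43 at percentile 99.9; after adjustment 10 were higher and 2 lower. The adjusted median was 1.43 as well, at percentile 100, but its interval of -0.74 to 2.33 spanned 0. Pim2, a kinase gene, was at 24.7 and 370 TPM and Pou3f1, which encodes the epiblast factor Oct6, at 5.31 and 78.0 TPM, whereas Fgf15 was at 23.5 and 8.48 TPM and Foxd3 at 49.3 and 29.7 TPM, the latter with a log2 ratio of 0.18 relative to the shift and -2.14 after adjustment. Fgf5, Otx2 and Dnmt3b, chosen after their values were seen, were at 0.770 and 3.63, 21.5 and 28.2, and 154 and 209 TPM.

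Of the 12 core pluripotency factors, 8 were at least 2-fold lower and 1 at least 2-fold higher in the T29I library as deposited, and 3 and 1 relative to the shift. Zfp42, also in the naive list, was the lowest at 544 and 23.3 TPM. Pou5f1, which encodes Oct4, was at 1722 TPM in the wild-type library (counting interval 1699 to 1746) and 1454 TPM in the T29I library (1435 to 1474), and Sox2 was at 563 and 355 TPM. Relative to the shift their log2 ratios were 0.65 and 0.23, and after adjustment -0.95 and -0.20, so neither has a direction that holds. Nanog was at 765 TPM (749 to 781) and 140 TPM (134 to 146), 5.45-fold lower in the T29I library. Rif1 was at 220 and 21.8, Dppa4 at 285 and 89.1, Sall4 at 197 and 66.4, Tdgf1 at 899 and 357, Lin28a at 221 and 87.7, and Dppa2 at 269 and 116 TPM. After adjustment the log2 ratio of Rif1 was -0.57 and that of Dppa2 -0.013. Trim28 was at 1781 and 1542 TPM. Utf1 was at 972 and 2459 TPM, but its adjusted log2 ratio was -0.40. The list median was -0.43 relative to the shift, at percentile 0.29, and -0.43 after adjustment (-1.22 to -0.34), at percentile 2.82.

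**Figure D2:**
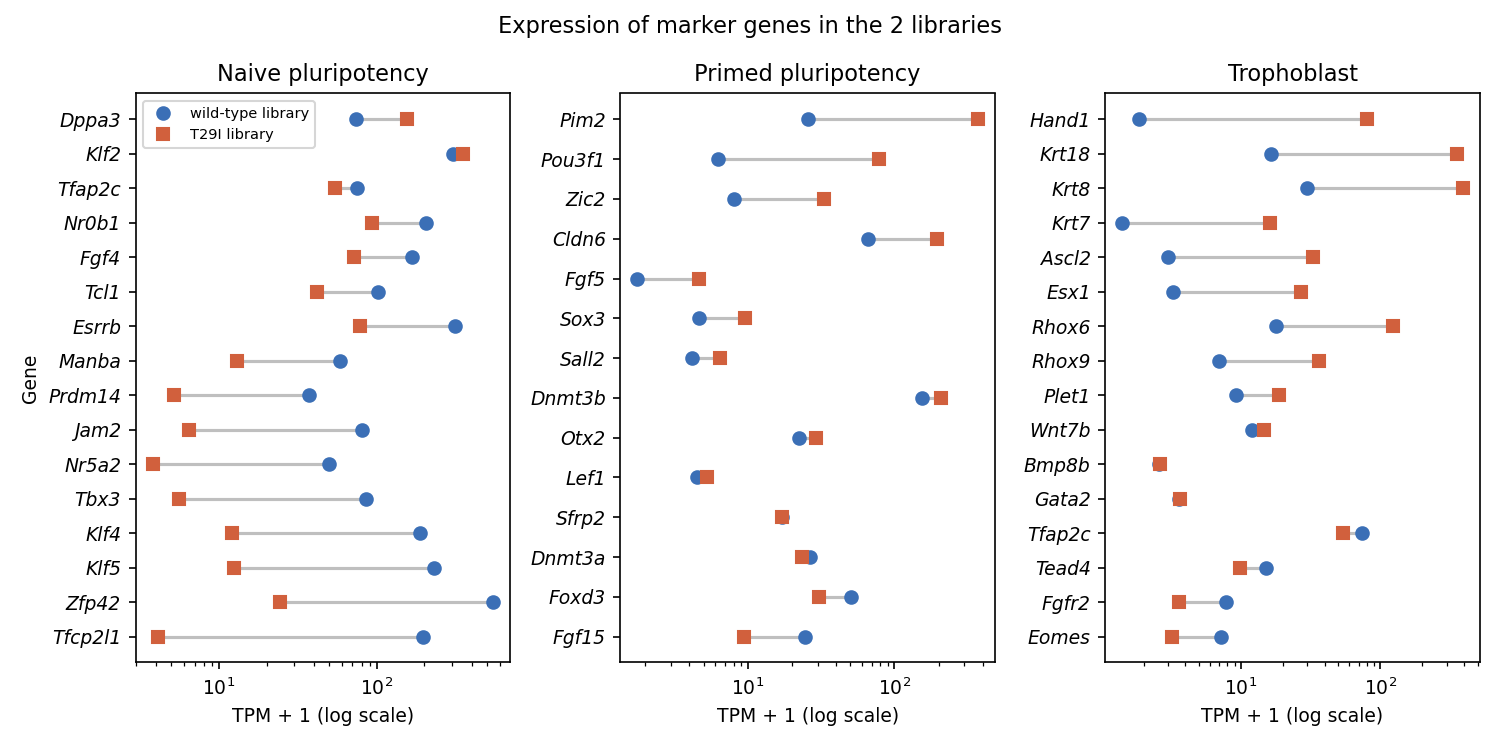
TPM + 1 on a log x axis for the members of the naive, primed and trophoblast marker lists with a mean of at least 1 TPM, with 1 point per library and a line joining the 2 libraries. Tfcp2l1 was at 194 TPM in the wild-type library and 3.11 TPM in the T29I library, and Hand1 was at 0.868 and 79.5 TPM.

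Genes of the 2-cell-like state, a rare state of ES cultures that resembles the embryo after its first division, were lower in the T29I library. Of 20 measured members, 11 were at least 2-fold lower relative to the shift and 0 at least 2-fold higher. Zscan4f was at 22.0 and 0.541 TPM, and Zscan4c at 10.3 and 0 TPM; the Zscan4 genes are near-identical copies and share reads. On the log2(TPM + 1) scale, which understates differences of low genes, the least different members were Arg2 at 1.89 and 0.530 TPM and Tcstv1 at 1.79 and 0.325 TPM. The list median was -1.17 relative to the shift, at percentile 0, and -1.07 after adjustment (-1.42 to -0.62). Copies that share reads are not independent members, which the percentile and the interval do not take into account. All 20 members reached 1 TPM in the wild-type library but only 3 in the T29I library, so most entered the list through the wild-type library.

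Trophoblast markers were higher in the T29I library, where the simple-epithelial keratin genes Krt8 and Krt18 were the most abundant of the list. Of 16 measured members, 10 were at least 2-fold higher relative to the shift and 0 at least 2-fold lower, with a median of 2.60 at percentile 100 and an adjusted median of 2.15 (0.13 to 3.34). Krt18 was at 15.4 and 353 TPM and Hand1 at 0.868 and 79.5 TPM. Krt8, also a primitive endoderm marker in these lists, was at 28.6 and 389 TPM. Eomes, a trophoblast and mesoderm factor, was at 6.21 and 2.19 TPM and Fgfr2 at 6.84 and 2.61 TPM, although the adjusted log2 ratio of Fgfr2 was 0.12. That value shows no higher level of Fgfr2 in the T29I library, because the log2(TPM + 1) scale compresses so low a gene.

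Markers of the other lineages went in both directions. Among 13 primitive endoderm markers, Lama1 was at 33.8 and 0.588 TPM and Lamc1, a second laminin gene, at 179 and 14.7 TPM, against the higher keratins; the list median was 0.30 relative to the shift and 0.15 after adjustment. Of 7 measured mesoderm and primitive streak markers, Bmp4 was at 36.6 and 4.63 TPM, Cdx1 at 7.82 and 1.12 TPM and Fgf8 at 0.713 and 5.05 TPM, and the list median was 0.42 relative to the shift and -0.56 after adjustment. The 5 measured neuroectoderm markers had medians of 1.03 and 1.27, with Neurog1 at 0.929 and 6.20 TPM, Rax at 0.693 and 2.90 TPM, Nes at 4.98 and 5.28 TPM and Sox21 at 3.40 and 2.31 TPM. The 8 measured definitive endoderm and pancreas markers had medians of 1.10 and 0.78. In that list, Ctrb1, a chymotrypsinogen, was listed at 0 in the wild-type library and had an estimated 58 reads in the T29I library, and Cela2a, a pancreatic elastase, was at 0.447 and 4.48 TPM. Ctrl was at 2.83 and 0.131 TPM and Cxcr4 at 3.20 and 1.26 TPM. The 20 germline genes had medians of 0.19 and 0.50, from Ddx4 at 23.2 and 3.67 TPM and Stra8 at 11.4 and 2.69 TPM to Rhox2a at 0.228 and 5.02 TPM and Rhox5 at 122 and 727 TPM. None of the 34 Hox genes in the Polycomb target list had a mean of at least 1 TPM. Among 16 genes of epithelial adhesion and its loss, with medians of 0.97 and 0.61, Cdh1, which encodes E-cadherin, was at 238 and 54.6 TPM, Zeb1 at 3.24 and 0.524 TPM, and Krt18 and Krt19 were the highest. The adjusted log2 ratio of Zeb1 was 0.42, which shows no higher level in the T29I library, because the log2(TPM + 1) scale compresses so low a gene.

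Proteases and their inhibitors were included because the mutated gene encodes a protease. The 16 measured serine protease inhibitors had a median of 1.01 relative to the shift, at percentile 98.2, and 0.64 after adjustment (-0.65 to 1.84), at percentile 96.8. Serpinf1 was at 0.408 and 7.70 TPM, while Serpinb6c was at 36.7 and 3.05 TPM and Serpinb9b at 8.57 and 0.858 TPM. Of 18 other serine proteases, 11 were at least 2-fold higher relative to the shift and 0 at least 2-fold lower, with a median of 1.15 at percentile 99.8. After adjustment 7 were higher and 2 lower, with a median of 0.76 (-0.63 to 1.32) at percentile 99.2. Prss50 was at 4.37 and 34.5 TPM and Hpn, a membrane protease, at 3.10 and 18.0 TPM, while Prss35 was at 5.54 and 0.791 TPM and Prss22 at 2.48 and 0.114 TPM. The adjusted intervals of both lists spanned 0.

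Genes of glycolysis and hypoxia, interferon-stimulated genes and replication-dependent histones were higher in the T29I library. Of 31 genes of glycolysis and hypoxia, 21 were at least 2-fold higher relative to the shift and 2 at least 2-fold lower. The lactate transporter gene Slc16a3 was at 29.2 and 267 TPM, and Gapdh, chosen after its values were seen, at 512 and 1388 TPM, while Hk2, a hexokinase, was at 87.04 and 18.1 TPM and the hypoxia-induced demethylase Kdm3a at 48.4 and 7.91 TPM. The median of that list was 1.80, at percentile 100, and 1.39 after adjustment (0.73 to 1.66). Eno1, the second highest member as listed, can share reads with Eno1b. The summed TPM of the pair differed far less than Eno1 alone, but that sum mixes unlike gene lengths. The pair held an estimated 50756 reads in the wild-type library and 146441 in the T29I library. Of 19 interferon-stimulated genes, 15 were at least 2-fold higher relative to the shift and 2 at least 2-fold lower, with a median of 2.15 at percentile 100 and an adjusted median of 1.32 (0.84 to 2.21). Psmb8, an immunoproteasome subunit, was at 0.0704 and 13.1 TPM and Gbp2, a guanylate-binding protein gene, at 0.0766 and 10.5 TPM, while the signal transducers Irf9 and Stat2 were at 12.7 and 2.28 TPM and at 16.3 and 3.37 TPM. Of 45 histone genes, 41 were at least 2-fold higher relative to the shift and 0 at least 2-fold lower; these short genes of high GC content had a median of 2.75. After adjustment 19 were at least 2-fold higher and 6 at least 2-fold lower, with a median of 0.83 (0.43 to 1.63). Histone copies share reads, and Hist1h4j and Hist1h2af were at 1.49 and 0.587 TPM and at 5.31 and 4.17 TPM. Of the 45 histone genes, 29 reached 1 TPM in the wild-type library and 44 in the T29I library. Of the 19 interferon-stimulated genes, 13 and 19 did. Some members of both lists thus entered through the T29I library, where they were higher. Psmb8 and Gbp2 had 1 estimated read each in the wild-type library.

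Relative to the shift and after adjustment, stress, growth and proliferation lists had smaller medians than the glycolysis, interferon and histone lists. Among 38 genes of the cell cycle, the median was -0.28 relative to the shift, at percentile 0.34, and -0.24 after adjustment (-0.57 to 0.17), at percentile 5.18. Mki67, which encodes the proliferation antigen Ki-67, was at 129 and 3.48 TPM and Cenpe, a kinetochore motor, at 56.2 and 1.22 TPM, whereas Ccnd3 was at 164 and 229 TPM and Cenpa at 130 and 172 TPM. The 24 p53 targets had a median of -0.52, at percentile 3.65, and of -0.69 after adjustment (-1.20 to 0.17), at percentile 0.37. Among them Mdm2, which encodes the ubiquitin ligase of p53, was at 73.8 and 5.45 TPM, and Polk at 13.6 and 0.518 TPM. Cdkn1a, a cell cycle inhibitor, was at 28.5 and 60.4 TPM, and Phlda3 at 80.2 and 138 TPM. The adjusted log2 ratio of Phlda3 was -0.70. Genes of the unfolded protein response had medians of 0.15 and 0.070 over 31 members. In that list the chaperone gene Hsp90b1 was at 607 and 82.9 TPM and Atf6, a stress sensor, at 23.3 and 3.51 TPM, while Chac1 and Trib3, both targets of the stress factors Atf4 and Chop, were at 5.06 and 32.1 TPM and at 20.7 and 60.8 TPM. The 16 heat shock genes had medians of 0.21 and -0.14, with Hsp90aa1 at 3747 and 804, Hspd1 at 1478 and 349, Hmox1 at 156 and 209, and Cryab at 2.47 and 17.3 TPM. Over 20 apoptosis regulators the medians were 0.25 and 0.16, with the inhibitors Birc2 and Xiap at 31.7 and 2.79 TPM and at 19.5 and 2.75 TPM and the activators Bmf and Bik at 4.14 and 10.4 TPM and at 7.56 and 16.2 TPM. The adjusted log2 ratio of Xiap was 0.0061, on a scale that compresses differences of low genes. The 24 immediate early genes had a median of 1.09, at percentile 99.55, and of 0.28 after adjustment, at percentile 85.25. They ran from Spry4 at 110 and 10.7 TPM and Spry2 at 114 and 32.7 TPM to Jund at 92.9 and 313 TPM and Ier3 at 14.3 and 155 TPM. The adjusted log2 ratio of Jund was -0.40.

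Cholesterol synthesis genes were split, with medians of -0.016 relative to the shift and -0.0052 after adjustment over 25 members. Idi1, an isomerase of the pathway, was at 184 and 14.9 TPM and Stard4, a sterol carrier, at 26.3 and 2.93 TPM, while the synthase gene Fdps was at 198 and 582 TPM. The 13 mitochondrially encoded genes summed to 10.7% of the wild-type TPM and 17.3% of the T29I TPM, with mt-Nd3 at 3384 and 11758 TPM, mt-Co3 at 11592 and 39428 TPM, mt-Nd4l at 2481 and 520 TPM and mt-Cytb at 6251 and 3479 TPM. Their median was -0.49 as deposited and 0.41 relative to the shift, at percentile 10.1. After adjustment it was 1.03 (0.63 to 3.13), at percentile 99.4, so the place of these genes among random lists depends on the adjustment. The 77 cytosolic ribosomal protein genes summed to 14.4% and 17.3% of the TPM, with medians of 0.98 and 0.092. Rpl4 was at 4300.4 and 838 TPM and Rps24 at 4374 and 942 TPM, against Rps14 at 1872 and 5391 TPM and Rpl29 at 511 and 1404 TPM; many ribosomal protein genes have processed pseudogenes that can take reads.

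Among imprinted genes H19 was far higher in the T29I library, and among regulators of DNA methylation Tet2 was far lower. Of 29 imprinted genes, 14 were at least 2-fold higher and 6 at least 2-fold lower relative to the shift, with a median of 0.81 at percentile 98.4 and an adjusted median of 0.82 (0.22 to 1.78), while the median as deposited was -0.084. H19 was at 8.61 TPM (counting interval 7.08 to 10.4) and 967 TPM (952 to 983), and Ascl2, a trophoblast factor, at 2.02 and 32.0 TPM, while Grb10, a growth inhibitor, was at 72.0 and 5.03 TPM and Igf2r at 36.7 and 3.27 TPM. The 15 genes of DNA methylation and demethylation had medians of -0.63 and -0.65 (-1.41 to 1.38 after adjustment). The adjusted log2 ratio of Tet2 was -2.78. Tet1, which also oxidises 5-methylcytosine, was at 160 and 8.53 TPM, but its log2 ratio of -4.08 came to -0.59 after adjustment, whereas Dnmt3l, a cofactor of the de novo methyltransferases, was at 206 and 568 TPM and Mbd3 at 206 and 345 TPM. The adjusted log2 ratio of Mbd3 was -0.66.

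Signalling target lists had medians on both sides of the median gene. The 11 Wnt targets had medians of -0.74 and -0.86 (-2.93 to 1.57 after adjustment), from Mllt6 at 113 and 5.24 TPM to Nkd1 at 0.254 and 1.76 TPM and Wnt8a at 0.883 and 3.81 TPM. For 17 targets of FGF and ERK the medians were 0.32 and -0.49, with Spry4 and Il17rd, both feedback inhibitors, at 110 and 10.7 TPM and at 25.4 and 2.80 TPM and Dusp5 and Ier3 at 8.02 and 20.99 TPM and at 14.3 and 155 TPM. The 16 targets of LIF and STAT3, the cytokine pathway that maintains mouse ES cells, had medians of 0.27 and -0.28, with Tfcp2l1 and Klf4 the lowest and Krt19 and Gadd45g, the latter at 1.81 and 25.6 TPM, the highest. The 19 targets of TGF-beta, Nodal and BMP had medians of 0.59 and 0.66, with Lefty1, a Nodal antagonist, at 91.4 and 478 TPM, and Bmp4 and Tgfbi, the latter at 10.9 and 1.81 TPM, the lowest.

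Markers of fibroblasts, the cells used as feeder layers, were mostly higher relative to the shift. Of 16 members, 13 lay above the shift, 8 were at least 2-fold higher and 2 at least 2-fold lower. The medians were 1.00, at percentile 98.0, and 0.86 after adjustment (-0.12 to 1.53), at percentile 99.1, with the smooth muscle genes Cnn1 and Acta2 at 1.83 and 14.2 TPM and at 1.51 and 12.1 TPM, and Fn1, which encodes fibronectin, and Fstl1 at 233 and 26.2 TPM and at 42.2 and 7.73 TPM. The fibrillar collagens Col1a1, Col1a2 and Col3a1, chosen after their values were seen, summed to 1.43 TPM in the wild-type library and 1.82 TPM in the T29I library. Of the 8 measured Y-linked and X-inactivation genes, Eif2s3x and Kdm6a, both X-linked, were at 423 and 41.5 TPM and at 40.2 and 4.04 TPM. The antisense RNA of Xist, Tsix, was at 5.67 and 0 TPM, and Kdm5c was at 78.5 and 26.2 TPM with an adjusted log2 ratio of 0.0082. The Y-linked genes Ddx3y and Uba1y were at 0.370 and 2.78 TPM and at 1.43 and 1.91 TPM. The list medians were -0.35 and 0.49.

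**Figure D3:**
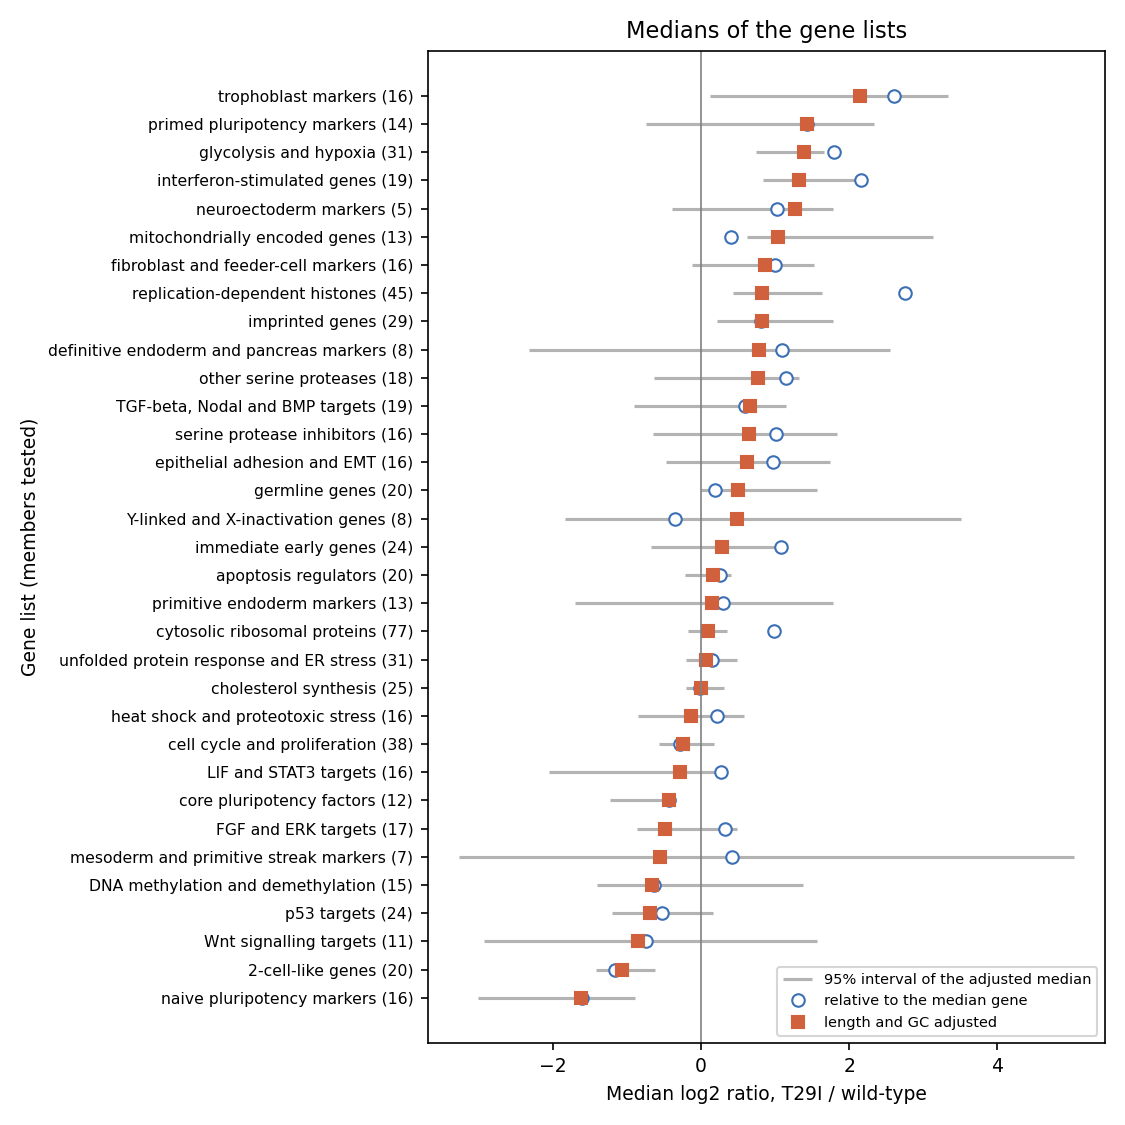
Median log2 ratio (T29I over wild-type) of each gene list with at least 5 measured members, relative to the median gene (open circles) and after adjustment for length and GC content (squares, with the 95% binomial interval over genes). Trophoblast markers had the highest adjusted median, 2.15, and naive pluripotency markers the lowest, -1.61.

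Genes of chromosomes 6 and 11 were higher in the T29I library than those of the other chromosomes once length and GC content were taken into account. Relative to the median shift, chromosome medians ran from -0.69 for chromosome 18 to 0.70 for chromosome 7, and across the 20 chromosomes they followed the median GC content of their genes (Spearman's rho 0.90). After adjustment the median of chromosome 11 was 0.39 (95% interval 0.33 to 0.48, 832 genes) and that of chromosome 6, which carries Prss1, 0.41 (0.26 to 0.51, 363 genes). The other chromosomes had adjusted medians from -0.26 to 0.11. Along chromosome 11, 32 of 33 windows of neighbouring genes had an adjusted median above 0, and along chromosome 6, 11 of 14 did. Hand1, Krt19, Car4 and Igfbp4, all among the 12 genes with the highest ratios, lie on chromosome 11. The medians of chromosomes 17 and 19 were 0.33 and 0.34 relative to the shift and -0.032 and -0.019 after adjustment.

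**Figure D4:**
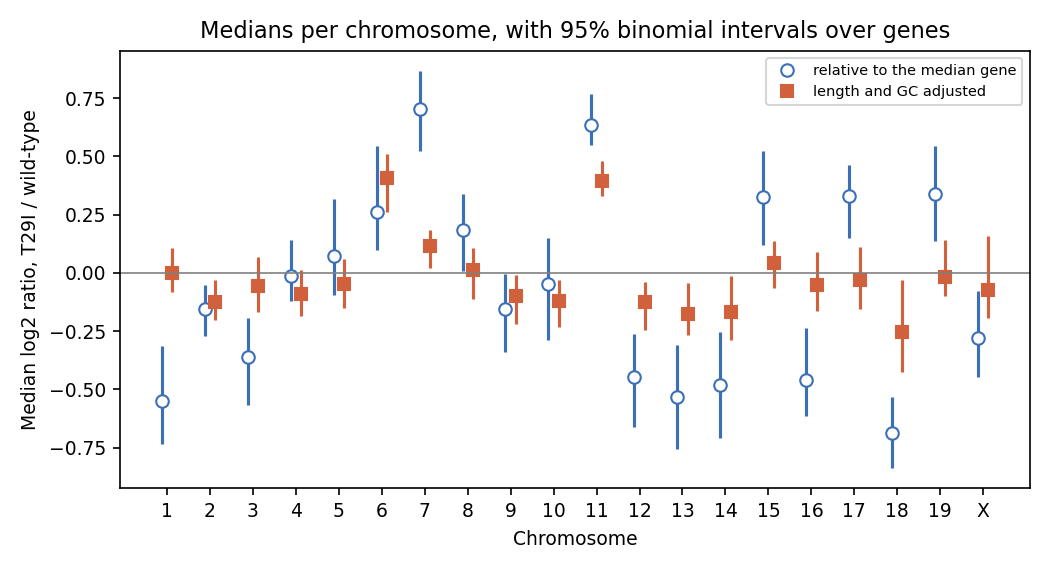
Median log2 ratio (T29I over wild-type) of genes with a mean of at least 5 TPM on each chromosome, relative to the median gene (open circles) and after adjustment for length and GC content (squares), with 95% binomial intervals over genes. After adjustment chromosomes 6 and 11, at 0.41 and 0.39, stand above the others, which lie between -0.26 and 0.11.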

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

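The length and GC adjustment was chosen after the data were seen; all other settings were fixed before. No paired analysis was possible because each group has 1 library and no replicate could be left out. Against 1290 genes at least 2-fold higher and 5909 at least 2-fold lower as deposited, median centring gave 3371 and 2867, TMM scaling 3221 and 3485, upper-quartile scaling 3598 and 3172, and the length and GC adjustment 2268 and 2003. These settings take out the library-wide shift. A minimum mean of 10 TPM gave 736 and 3355, with fewer genes tested, and a pseudocount of 5 gave 749 higher genes. A pseudocount of 0.1, no filter, a minimum mean of 5 TPM and leaving out small RNAs and predicted genes kept both counts within 1.5 times. The imprinted list, with a median of -0.084 as deposited, was at 0.81 after median centring, 0.56 with TMM scaling, 0.67 with upper-quartile scaling, 0.82 after adjustment and 0.40 with a minimum mean of 5 TPM. The immediate early list went from 0.19 to -0.072 with that minimum. Among named genes with a mean of at least 1 TPM and at least 2-fold apart as deposited, adjustment turned the log2 ratios of Fgfr2 (0.12), Jund (-0.40), Kdm5c (0.0082), Utf1 (-0.40), Xiap (0.0061) and Zeb1 (0.42) and upper-quartile scaling turned Pcna (0.051). The turned values of Kdm5c and Xiap lay near 0. Fgfr2, Xiap and Zeb1 were at 2.61, 2.75 and 0.524 TPM in the T29I library, where the log2(TPM + 1) scale compresses the ratio. Their turned values thus show no higher level in that library. Adjustment also turned smaller differences, such as those of Klf2 (-0.89), Mbd3 (-0.66), Phlda3 (-0.70) and Ctsl (1.37), and the medians of chromosomes 17 (-0.032) and 19 (-0.019). Beyond the removal of the shift and of the trend and the compression of low genes, the cause was not tested. Scaling cannot move the 0 TPM of Prss1, so no setting tests it. Depth limits statements on genes with few reads.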

Other observations

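The length and GC tests and the collagen test were chosen only after the result was seen. The tests of depth, abundant genes, a subset of chromosome 11 genes and copy number were written before their own results. Both of these chromosome 11 tests still used an adjustment and a chromosome picked after the data were seen. All genes named in the next paragraph were chosen after their values were seen, apart from Hbb-bs.

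Hbb-bs was far above the other globin genes in the T29I library. It was at 1245 TPM in the T29I library from an estimated 6316 reads (counting interval 1214 to 1276 TPM) and at 0 in the wild-type library. Hba-a1 was at 0 in the wild-type library and 8.02 TPM in the T29I library, from 43 estimated reads, and Hba-a2 at 0.866 and 1.13 TPM. Hbb-bt, Hbb-y and Hbb-bh1 were at 0 in the wild-type library and at 0.861, 0.957 and 0.988 TPM in the T29I library, from 4 estimated reads each, too few to show a difference, and such similar genes can take reads from Hbb-bs. Whether the Hbb-bs reads came from the endogenous gene, from an introduced sequence or from other cells was not tested. Alas2, the heme synthesis enzyme of red cell precursors, was at 0.160 TPM in the wild-type library and 0 in the T29I library. Y-linked genes were low in both libraries, with Eif2s3y at 0.602 and 1.02 TPM, Kdm5d at 0.0747 and 0.0822 TPM, Uty at 0.0752 and 0.906 TPM, and Zfy1 at 0 and 0.369 TPM. Xist, the X-inactivation RNA, was at 1.33 TPM in the wild-type library and 0 in the T29I library. Its adjusted log2 ratio of 2.75 shows no higher level in the T29I library, because the log2(TPM + 1) scale compresses so low a gene. Lars2 was at 81.5 and 340.1 TPM.

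The library-wide shift and its trend with length and GC content do not come from depth alone. Among protein-coding genes with a mean of at least 100 TPM, which many reads cover, the longest 20% lay -1.52 (95% bootstrap interval -1.81 to -1.34) from the shortest 20% on the log2 scale. Leaving out the 20 most abundant genes and rescaling left a median log2 ratio of -0.72 (-0.76 to -0.68), so those genes are not the whole cause. A bias from RNA quality or library preparation may underlie the 44.9% of variance that length and GC content accounted for, but with 1 library per group it cannot be told apart from a difference between the cells. A biological difference between wild-type and T29I cells was not tested and stays open.

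Naive markers were lower and primed markers tended to be higher in the T29I library, and whether the cells differed in pluripotent state was not tested. The length and GC trend is not the whole cause for the naive list, whose adjusted median was -1.61 (-3.01 to -0.89), below all random lists. The primed median was 1.43 both before and after adjustment, at percentile 100 of random lists after it, which argues against the trend as the whole cause, but the adjusted interval of -0.74 to 2.33 spans 0 and leaves it open. A culture taken over by fibroblasts or feeder cells is argued against by Col1a1, Col1a2 and Col3a1, which summed to 1.82 TPM in the T29I library. Clone, culture conditions and the T29I genotype are confounded and stay open.

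Genes of chromosome 11 were higher in the T29I library by an adjusted median log2 ratio of 0.39 (0.33 to 0.48), which remained after the length and GC trend was removed. A few strongly different genes do not account for it, since the 25th percentile of the chromosome was also displaced, by 0.46 (0.36 to 0.54) from the chromosomes other than 6 and 11. The displacements at the 50th and 75th percentiles were 0.45 and 0.40. All 3, the largest 0.46, lay in the range set for a higher chromosome 11 copy number in part or all of the T29I culture. That outcome adds little support, because chromosome 11 was picked for its higher genes in these same data. Chromosome 6 had displacements of similar size, at 0.40, 0.46 and 0.55. Copy number was inferred from RNA alone, and whether a gain came with the mutation, the clone or passage was not tested.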
